A study of Capra hircus with 6 samples.

How the data were processed

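Total RNA of peripheral blood mononuclear cells from goat kids (Capra hircus) was extracted with TRIzol, and libraries were made with an NEBNext Ultra II RNA kit, per the labels' protocols. Whether transcripts were selected by poly(A) or ribosomal RNA was depleted, and the strand setting of the counting, are not given in the sources used here. The authors deposited raw counts per gene for 6 libraries in 1 table, as whole numbers. Per the submitters' processing notes, the tools were bcl2fastq 2.19.0.316, FastQC 0.11.9, MultiQC 1.12, fastp 0.22.0, STAR 2.7.10a and featureCounts 2.0.0. Their parameters, the genome build and the annotation are not given in the sources used here. Without a stated strand setting, overlapping antisense genes cannot be told apart, and near-identical gene copies can share or lose reads.

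The table held 24779 rows, 0 of which named no gene, and 6603 of which are listed only by a LOC number. Columns were matched to samples by the sample descriptions, and groups and replicate numbers came from the sample titles. Totals ran from 25023210 to 57204363 counts per library. Gene span, chromosome and biotype came from the RefSeq gene table of the ARS1.2 assembly, which held 23022 of the genes (92.9%). No coordinates are printed, since the authors' build is not known. Counts per kb were taken over 12142 autosomal protein-coding genes and 337 X-linked genes of at least 10 kb. A library was called span-proportional where the Spearman correlation of its counts with gene span was above 0.6, a rule made after seeing the data.

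Genes were filtered with filterByExpr, scaled with TMM and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, replacer milk minus doe milk, two-sided, with Benjamini-Hochberg adjusted p below 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM are counts divided by the library total on the usual CPM scale. Before the data were examined, 40 gene lists were fixed, 39 of them for testing (12 cell type marker lists and 27 pathway lists) and 1 of sex-linked genes as a control, of which SRY is in the table. Of their 805 members, 670 are in the table. The 38 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, ranks and fry beside it. The gamma-delta T cell list had 4 tested members and entered the marker levels only. Marker levels are means over members of log2 CPM with a prior count of 2, compared by an exact permutation test over 10 splits. Random lists, 10000 per list, were drawn from genes matched on mean expression. The share of even counts from 2 to 9 was set against that with the number of genes at each count smoothed over neighbouring counts on a log scale.

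Named genes followed a rule fixed before the data were examined. With fewer than 6 genes passing, it takes the 10 genes with a symbol and the smallest p, as values, and, for each list past the camera threshold or with a called member, up to 4 members with the smallest p. Fewer members were named for most lists. It was applied in the same way to the transcript-like libraries, where members that passed when adjusted over the list alone were counted as called. Other genes are said to have been chosen after their values were seen.

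The gene and list tests were tested on simulated data drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. Each gene was drawn independently and the simulated lists held random genes. False calls of lists whose genes vary together were therefore not measured. With all 6 libraries mixed as deposited, edgeR recovered 0% of both and DESeq2 0% of both. With 6 libraries all transcript-like, edgeR recovered 31% and 99%. A raised list had a camera adjusted p of 0.295 in the mixed libraries and 3.88e-05 in 2 against 1 transcript-like libraries, and 0 of 30 unchanged lists were called in either.

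Alternatives fixed beforehand were RLE and upper quartile scaling, no filter, at least 1 CPM in every library, the replicate number as a block, each library left out, abundant genes left out, DESeq2 1.42.0, limma voom, dispersions not robust, other thresholds, and for lists an estimated correlation, fry and ranks. Library kind as a term, replacer-milk libraries 2 and 3 summed or averaged, and the comparisons within each kind were added after seeing the data. Figures were drawn with matplotlib 3.10.9.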

Results

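Peripheral blood mononuclear cells, the lymphocytes, monocytes and dendritic cells of the blood, were compared between goat kids fed doe's milk (control, 3 libraries) and goat kids fed milk replacer (test, 3 libraries). The design asks which genes the cells expressed differently under the 2 feeds. The labels call the libraries biological replicates. Counts were given for 24779 genes. The total count was 48063350, 57204363 and 25023210 in doe-milk libraries 1, 2 and 3, and 51893874, 27129143 and 26690109 in replacer-milk libraries 1, 2 and 3.

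The 6 libraries were of 2 kinds, and the kinds crossed the feeds. In doe-milk libraries 1 and 2 and replacer-milk library 1, blood cell transcripts led the counts. B2M, the light chain of MHC class I, stood at 10105, 9602 and 8383 CPM (counts scaled to a common library total) in these 3 libraries, and the translation factor EEF1A1 was the most counted gene in each. In doe-milk library 3 and replacer-milk libraries 2 and 3, B2M stood at 4.88, 2.99 and 4.42 CPM. The B cell receptor component CD79A stood at 610, 526 and 714 CPM in the first 3 libraries and at 1.40, 1.47 and 1.42 CPM in the others. Genes of other tissues went the opposite way. The muscle gene DMD, one of the longest genes known, had 4.64, 4.67 and 5.65 CPM against 1569, 1347 and 1363 CPM, and the liver gene ALB had at most 0.175 CPM against 19.0, 45.6 and 45.4 CPM. Not every abundant gene was lost. UBB, a ubiquitin gene, stood at 3893, 4304 and 3659 CPM in the first 3 libraries and at 1641, 3169 and 2901 CPM in the others. These genes were chosen after their values were seen.

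In the second kind of library the counts followed the genomic span of the gene, introns included, as listed for 92.9% of the genes in the ARS1.2 assembly. Across genes, which are not independent replicates, the Spearman correlation of counts with span was 0.893, 0.896 and 0.896 in doe-milk library 3 and replacer-milk libraries 2 and 3. It was 0.374, 0.387 and 0.380 in doe-milk libraries 1 and 2 and replacer-milk library 1. The first 3 are called span-proportional from here on and the other 3 transcript-like. Mitochondrially encoded transcripts took 2.08% (95% Wilson interval 2.076 to 2.084), 3.30% (3.29 to 3.30) and 1.98% (1.97 to 1.98) of the counts in doe-milk libraries 1 and 2 and replacer-milk library 1. They took 0.00125% (0.00112 to 0.00140), 0.00133% (0.00120 to 0.00147) and 0.00129% (0.00116 to 0.00143) in doe-milk library 3 and replacer-milk libraries 2 and 3. These intervals cover counting error only. The Y-linked gene SRY had 0 counts in each transcript-like library and 12, 42 and 41 counts in the span-proportional ones. X-linked genes had a median of 0.856, 0.919 and 0.901 times the autosomal counts per kb in doe-milk library 3 and replacer-milk libraries 2 and 3. The sex of the kids was not tested with these values.

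**Figure D1:**
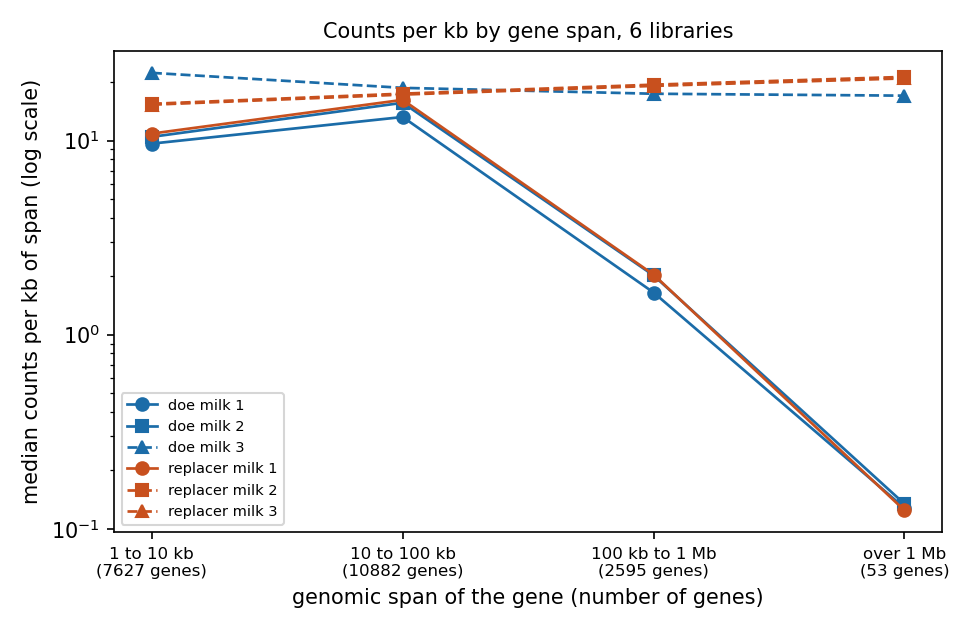
Median counts per kb of genomic span (vertical axis, log scale) for genes grouped by span (horizontal axis), 1 line per library, with doe milk in blue, replacer milk in orange, transcript-like libraries solid and span-proportional libraries dashed. Genes over 1 Mb had 0.128, 0.134 and 0.124 counts per kb in the transcript-like libraries and 17.0, 21.3 and 20.9 in the span-proportional ones.

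Libraries correlated by kind, not by feed. The Pearson correlation of log2 CPM across genes was 0.990 for each pair of transcript-like libraries, and doe-milk library 3 correlated at 0.882 and 0.883 with replacer-milk libraries 2 and 3 but at 0.376 and 0.383 with doe-milk libraries 1 and 2. Replacer-milk libraries 2 and 3 correlated at 0.997 with a chi-square of 2.80 per degree of freedom, where the other 2 pairs of span-proportional libraries gave 368 and 363 and the transcript-like pairs 97.2 to 127. In every library 61.2% to 66.9% of the counts from 2 to 9 were even, against 52.2% to 54.6% with the numbers of genes smoothed over neighbouring counts, a check added after seeing the data. The chi-square takes counts as single independent reads and does not settle whether these are separate samples. They were kept as 2 replicates as labelled, and p-values over them may measure technical spread. Counted as 1 library, they left the number of genes called between the feeds at 0 and gave 20 gene lists in place of 25, an alternative chosen after seeing the data.

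Over all 6 libraries, no gene passed the test between the feeds. Of 21431 genes tested with edgeR's quasi-likelihood test, 0 passed an adjusted p of 0.05, the smallest adjusted p was 0.987, and 123 had an unadjusted p below 0.05 (0.574%). DESeq2 called 2 genes and limma voom 0. The 2 were TNNC2, the calcium-binding troponin of fast skeletal muscle, and LOC108635454, which is listed without a symbol, both of them chosen after their values were seen. TNNC2 stood at 0.458, 0.664 and 1.84 CPM in the doe-milk libraries and at 0.462, 352 and 332 CPM in the replacer-milk libraries, so that replacer-milk library 1 lay with the controls. Replacer milk lay above doe milk in all libraries for 406 genes and below it for 231, together 2.97% of genes where chance gives 10%. In simulated counts with the same mixture of library kinds, edgeR recovered 0% of genes changed 4-fold, against 99% when all 6 simulated libraries were transcript-like.

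The 10 named genes with the smallest p were given as values because none passed. TARM1, a receptor of myeloid cells, had the smallest p, at 16, 9.999 and 28.3 CPM in the doe-milk libraries and 2.698, 2.36 and 2.10 CPM in the replacer-milk libraries (log2 fold change −3.04, SE 0.80, edgeR adjusted p = 0.987). The other 9 were higher in replacer milk in the fit, all with an edgeR adjusted p of 0.987. For each of these 9, replacer-milk library 1 lay below doe-milk library 3. Their rise came from replacer-milk libraries 2 and 3, both span-proportional. The log2 fold changes were 7.38 (SE 2.13) for TNNC2, 5.26 (SE 1.51) for the protease inhibitor CST6, 5.26 (SE 1.66) for the histidine-degrading enzyme AMDHD1 and 4.19 (SE 1.24) for the small GTPase RND1. They were 3.50 for the collagen receptor subunit ITGA10, 3.22 for the transporter SLC18B1, 3.19 for TTPAL, 2.98 for the actin-binding DBN1 and 2.702 for the transporter SLC45A3. For ITGA10, replacer-milk libraries 2 and 3 had 124 and 120 CPM, while replacer-milk library 1 had 5.40 CPM, below doe-milk library 3 at 10.1 CPM.

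Gene lists fixed before the data were examined were lower in replacer milk over all 6 libraries at a preset correlation. Of 38 lists tested with camera, 25 passed an adjusted p of 0.05 at a preset correlation, all lower in replacer milk, with list medians from −1.46 to −0.42 on the log2 scale. With an estimated correlation 0 passed (smallest adjusted p = 0.519), and 0 passed with fry (smallest adjusted p = 0.703). The replacer-milk group holds 2 span-proportional libraries of 3 and the doe-milk group 1 of 3. With library kind as a term, chosen after seeing the data, 1 list passed, without doe-milk library 1 or 2 the count was 13 or 14, and with at least 1 CPM in every library it was 8. No member of any list passed over all genes tested or adjusted over the list alone. Random lists matched on expression had negative medians too, at −0.85 for ribosomal proteins and −0.86 for mitochondrially encoded transcripts. For T cells the median was −0.63 against −0.50, and 31.5% of the random lists lay lower. For B cells 25.5% lay lower. Other lists, among them ribosomal proteins and the interferon response, lay below all 10000 random lists.

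The lists that passed over all libraries included housekeeping and immune functions. All 49 cytosolic ribosomal protein genes had negative fold changes (median log2 fold change −1.18). RPL24 had 1215, 1234 and 2.60 CPM in the doe-milk libraries and 895, 3.91 and 2.96 CPM in the replacer-milk libraries, and RPL38 had 564, 451 and 2.84 against 455, 3.61 and 2.96 CPM. This list was the one that passed with library kind as a term (median −0.74, camera adjusted p = 0.000366), a fit in which RPL38 had a log2 fold change of 0.043. Within the transcript-like libraries its median was only −0.18, and within the span-proportional ones −1.46. Its mean log2 CPM in the latter was low, at 3.09 in doe-milk library 3 and at 1.37 and 1.33 in replacer-milk libraries 2 and 3. All 17 oxidative phosphorylation genes had negative fold changes (median −1.12), with NDUFB3 at 66.2, 37.4 and 7.07 against 36.8, 4.76 and 4.12 CPM and NDUFA9 at 32.3, 45.7 and 23.0 against 37.2, 6.82 and 7.57 CPM. So had all 13 mitochondrially encoded transcripts (median −1.46), with ND1 at 860, 1851 and 0.879 against 719, 0.369 and 0 CPM. Of the interferon response genes, 28 of 30 were negative (median −1.31), and of the immediate early genes, 17 of 19 (median −1.46). The antiviral enzyme RSAD2 had 132, 115 and 12.2 CPM against 36.3, 7.74 and 10.3 CPM, and the nuclear receptor NR4A2 31.4, 23.9 and 12.99 against 14.1, 3.69 and 3.41 CPM.

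Most cell type marker lists separated by library kind, not by feed. The mean log2 CPM of 9 of the 12 marker lists was lower in replacer milk, and no list differed in an exact two-sided permutation test (p from 0.2 to 1 with 3 against 3 libraries, where the smallest possible is 0.1). The B cell list averaged 5.997 ± 2.15 (SD, n = 3) in doe milk and 4.45 ± 2.58 (SD, n = 3) in replacer milk, or 5.1995 ± 3.16 (SD, n = 2) with replacer-milk libraries 2 and 3 averaged as 1, an alternative chosen after seeing the data. By library it stood at 7.27, 7.21 and 3.51 in doe milk and at 7.43, 2.98 and 2.95 in replacer milk. The T cell list stood at 7.15, 7.001 and 2.96 against 7.24, 3.72 and 3.62, and the monocyte list at 5.73, 5.72 and 3.17 against 5.55, 2.80 and 2.85. The dendritic cell list, at 4.46, 3.52 and 3.93 against 3.50, 4.36 and 4.32, and the eosinophil and basophil list, at 3.35, 2.97 and 3.34 against 3.02, 3.95 and 4.01, did not separate by library kind. Members went both ways. The B cell transcription factors PAX5 and EBF1 had log2 fold changes of 1.16 (SE 0.78) and 1.33 (SE 1.07). GZMA, a granzyme of cytotoxic cells, had −1.77 (SE 0.88), and all had an edgeR adjusted p of 0.987. PAX5 stood at 34.7, 39.4 and 111 CPM in doe milk and at 49.6, 246 and 239 CPM in replacer milk. EBF1 stood at 56.7, 73.1 and 273 against 69.6, 587 and 601 CPM, so that both were higher in the span-proportional libraries.

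Within the transcript-like libraries, a comparison chosen after seeing the data, interferon response genes were lower in the library labelled replacer-milk 1 than in both doe-milk libraries. This sets doe-milk libraries 1 and 2 against replacer-milk library 1, so that the replacer-milk side is 1 library, whose label was not checked by any other value, and is assumed to vary like the other group. After TMM scaling, all 30 interferon response genes tested lay below both doe-milk libraries, where 33.2% of all genes did and chance gives 33.3%. That chance holds for each gene taken alone, and genes measured in 1 library are not independent replicates of the feed. The median log2 fold change was −0.74 (camera adjusted p = 1.48e-27 at the preset correlation), lower than all of 10000 random lists matched on expression. The call was lost with an estimated correlation (adjusted p = 0.712) and with fry (adjusted p = 0.232), both of which rest on 1 residual degree of freedom. The test at the preset correlation used the same fit, and its p-value measures spread among genes, not between animals. The random lists likewise do not measure spread between animals. In replacer-milk library 1 the erythroid markers had a median of −0.87, the neutrophil markers −0.43 and the platelet markers −0.26. The mean level of the list was 6.47 in each doe-milk library and 5.68 in replacer-milk library 1. Adjusted over the list alone, 18 of the 30 passed in edgeR, and over all genes tested 0 did. RSAD2 was at 132 and 115 CPM against 36.3 CPM (log2 fold change −1.88, SE 0.22). The ubiquitin-like ISG15 was at 1155 and 995 against 327 CPM (−1.83, SE 0.22), the antiviral GTPase MX2 at 131 and 100 against 42.5 CPM (−1.55, SE 0.25), and the interferon-induced IFIT3 at 113 and 82.8 against 33.3 CPM (−1.67, SE 0.27).

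**Figure D2:**
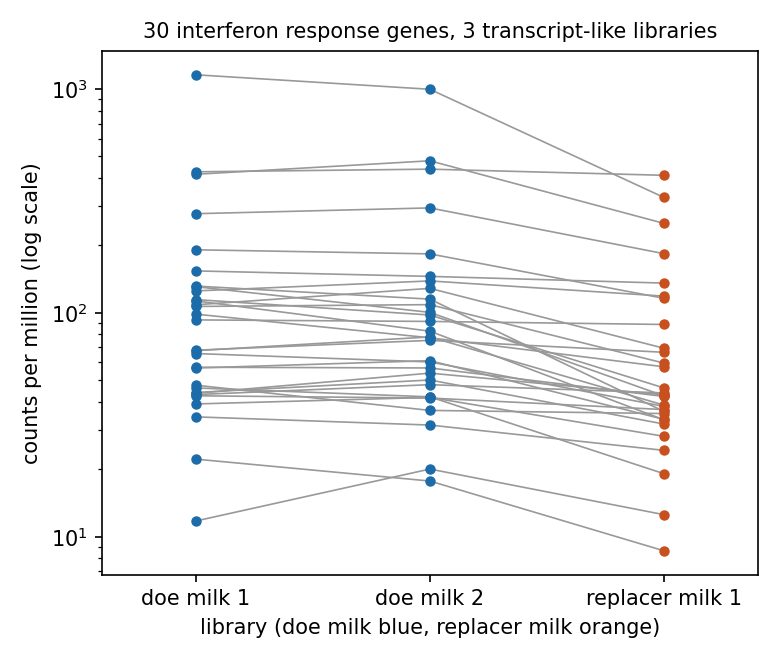
CPM (vertical axis, log scale) of the 30 tested interferon response genes in the 3 transcript-like libraries (horizontal axis), each point 1 gene in 1 library and each line joining the values of 1 gene. After TMM scaling, all 30 genes lay lower in replacer-milk library 1 than in either doe-milk library. The CPM drawn here are not TMM-scaled.

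Immediate early genes and inflammatory genes were also lower in replacer-milk library 1. Of 19 immediate early genes, 18 had negative fold changes and 16 lay below both doe-milk libraries (median −0.60, camera adjusted p = 1.62e-09, and adjusted p = 0.712 with an estimated correlation). The median was −0.39 without doe-milk library 1 and −0.83 without doe-milk library 2. Values were 31.4 and 23.9 against 14.1 CPM for NR4A2, 1179 and 879 against 579 CPM for the AP-1 subunit JUNB, 1036 and 817 against 552 CPM for the mRNA decay factor ZFP36, and 503 and 413 against 302 CPM for FOS. Of 24 inflammatory cytokine and NF-kB target genes, 21 were negative (median −0.51, camera adjusted p = 1.73e-05, and adjusted p = 0.712 with an estimated correlation), and 2 passed in edgeR when adjusted over the list alone. These were NFKBIA, the inhibitor of NF-kB, at 2089 and 1481 against 799 CPM (log2 fold change −1.27, SE 0.27), and the mitochondrial superoxide dismutase SOD2 at 321 and 361 against 190 CPM (−0.96, SE 0.21). The cyclooxygenase PTGS2 was at 130 and 115 against 84.2 CPM, and the chemokine CCL20 went the other way at 1.79 and 1.77 against 4.72 CPM. In the same library the neutrophil markers were lower by a median of −0.43 and the platelet markers by −0.26, as described next. The monocyte markers had a median of −0.22 and did not pass (camera adjusted p = 0.394), and the median was 0.064 without doe-milk library 1 and −0.071 without doe-milk library 2.

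Markers of cells that can be carried over with mononuclear cells, and those of plasma cells, were lower in replacer-milk library 1 as well. The erythroid list had a median log2 fold change of −0.87 (6 of 8 genes negative, camera adjusted p = 0.00936, adjusted p = 0.712 with an estimated correlation and 0.0764 with ranks). The beta-type globin HBBC was at 1619 and 1794 against 607 CPM (−1.60, SE 0.21) and passed in edgeR when adjusted over the list alone. ALAS2, an enzyme of heme synthesis, went the other way, at 1.93 and 5.12 against 9.62 CPM. Reads of HBBC can be shared with other globin genes. Neutrophil markers varied widely, with log2 fold changes of single members from −4.35 to 0.79. CXCR2 was at 163 and 58.8 against 16.6 CPM, and CSF3R at 249 and 117 against 70.2 CPM. The neutrophil list had a median of −0.43 (13 of 18 genes negative, camera adjusted p = 0.0109, adjusted p = 0.712 with an estimated correlation and 0.0520 with ranks), with the calcium-binding S100A9 at 206 and 157 against 107 CPM and LCN2 at 11.9 and 15.0 against 9.02 CPM. The platelet list had a median of −0.26 (13 genes, camera adjusted p = 0.0109, and adjusted p = 0.712 with an estimated correlation). The platelet median was −0.41 without doe-milk library 1 and −0.11 without doe-milk library 2. TREML1 passed in edgeR when adjusted over the list alone, at 30.1 and 26.9 against 14.9 CPM. PPBP, a platelet chemokine, was at 41.3 and 51.0 against 28.3 CPM. The plasma cell list had a median of −0.24 (12 genes, camera adjusted p = 0.0109, and adjusted p = 0.712 with an estimated correlation), with the immunoglobulin joining chain JCHAIN at 1201 and 777 against 535 CPM and the plasma cell receptor TNFRSF17 at 4.27 and 3.58 against 1.19 CPM.

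The other 4 lists that passed in the transcript-like libraries were the unfolded protein response, ribosomal proteins, the cell cycle and mitochondrially encoded transcripts. The unfolded protein response list had a median of −0.36 (18 genes, camera adjusted p = 0.00922, and adjusted p = 0.712 with an estimated correlation), with MANF at 46.1 and 38.4 against 25.7 CPM and CRELD2 at 33.5 and 27.0 against 20.9 CPM. The ribosomal protein list had a median of −0.18 (44 of 49 genes negative, camera adjusted p = 0.00922, and adjusted p = 0.712 with an estimated correlation), with RPL24 at 1215 and 1234 against 895 CPM. The cell cycle list had a median of −0.23 (29 of 32 negative, camera adjusted p = 0.0452, and adjusted p = 0.712 with an estimated correlation), −0.31 without doe-milk library 1 and −0.12 without doe-milk library 2, with RRM2, a subunit of ribonucleotide reductase, at 23.1 and 19.6 against 12.8 CPM. The mitochondrially encoded list had a median of −0.46 (11 of 13 negative, camera adjusted p = 0.0128, and adjusted p = 0.712 with an estimated correlation). COX1 was at 8394 and 11780 against 7031 CPM. The list median was −0.79 without doe-milk library 1 and −0.04 without doe-milk library 2, and it differed by 0.76 between the doe-milk libraries themselves. No list was higher in replacer-milk library 1 past the threshold.

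Lymphocyte lists went both ways in replacer-milk library 1 without passing. The list of naive and memory lymphocyte markers had a median of 0.16 (camera adjusted p = 0.0575), B cells 0.14 (adjusted p = 0.0819), and T cells 0.11 (adjusted p = 0.135). The cytotoxic T and NK cell list had a median of −0.18, with 11 of 16 members negative (adjusted p = 0.878), though its mean was 0.02 and the camera direction upward. The direction of some depended on the doe-milk library. Without doe-milk library 1 the median was 0.04 for naive and memory lymphocytes, 0.22 for B cells, 0.21 for T cells and −0.46 for cytotoxic T and NK cells. Without doe-milk library 2 it was 0.27, 0.15, −0.04 and 0.26. A few members passed in edgeR when adjusted over the list alone. BACH2, a repressor that maintains naive lymphocytes, was at 66.7 and 68.3 against 147 CPM (log2 fold change 1.01, SE 0.19), and the complement receptor CR2 of B cells at 6.87 and 5.56 against 25.7 CPM (1.94, SE 0.26). In the list of Fc receptors and immunoglobulin transport, members that passed in this way were the IgM receptor FCMR at 381 and 301 against 645 CPM and the neonatal Fc receptor FCGRT at 27.5 and 22.0 against 47.6 CPM. So did the IgE receptor FCER2 at 34.5 and 32.8 against 58.3 CPM, which did not pass within the B cell list. The Fc receptor list itself did not pass. It had a median of 0.43 with 5 of 8 members positive, but a mean of 0.01, and PIGR went the other way (−1.35). The dendritic cell list had a median of −0.68, with 8 of 10 members negative (adjusted p = 0.292), but 0.005 without doe-milk library 1 and −1.197 without doe-milk library 2. Its member IRF8, a transcription factor of B cells and dendritic cells, went the other way, at 68.2 and 65.5 against 134 CPM, and passed in edgeR when adjusted over the list alone. On the lower side were the monocyte lectin CLEC4E at 17.9 and 22.0 against 5.63 CPM (−1.94, SE 0.29) and the glucocorticoid-responsive CRISPLD2 at 49.1 and 47.1 against 25.7 CPM (−1.02, SE 0.22). Antigen presentation, heat shock, hypoxia, fatty acid oxidation and cholesterol synthesis lists had medians between −0.11 and −0.01 and camera adjusted p-values from 0.878 to 0.968, and the camera direction was upward, against the sign of the median, for antigen presentation and heat shock. Against single doe-milk libraries these medians ran from −0.375 to 0.279, and all but that of antigen presentation differed in sign between the 2 libraries.

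Gene by gene, 3 of 17356 genes tested in the transcript-like libraries passed in edgeR. All 3 lack a gene symbol and were named after their values were seen. LOC102181554 was at 94.96 and 100.5 against 0.771 CPM (log2 fold change −7.09, SE 0.31, adjusted p = 0.00651), LOC102186914 at 257 and 227 against 24.3 CPM (−3.42, SE 0.24, adjusted p = 0.0359), and LOC108637289 at 4.473 and 4.9996 against 53.9 CPM (3.40, SE 0.22, adjusted p = 0.0359). DESeq2 called 143 genes and limma voom 0. Among genes with a symbol, the smallest p belonged to HCAR2, the receptor for niacin and beta-hydroxybutyrate, at 359 and 375 against 88.0 CPM (−2.17, SE 0.21, adjusted p = 0.145). The 9 that followed, with adjusted p from 0.202 to 0.261, included RSAD2, ISG15, HBBC and CR2. The others were AMPH (−2.25), the Fc receptor-like FCRL3 (−1.76) and TMEM158 (−1.69) on the lower side, and the lipoprotein receptor LSR (2.15) and SHISA8 (1.73) on the higher side. In simulated counts of this 2 against 1 design, edgeR recovered 3% of genes changed 2-fold and 42% of genes changed 4-fold. Genes left unchanged were called there too, by edgeR and by DESeq2.

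The span-proportional libraries, doe-milk library 3 against replacer-milk libraries 2 and 3, gave 16266 called genes of 22232 tested, 8158 higher and 8108 lower in replacer milk (edgeR, chosen after seeing the data). The count compares these libraries, not the feeds, since doe-milk library 3 is set against a spread taken from replacer-milk libraries 2 and 3 alone, which were near counting noise. The biological coefficient of variation in that fit was 0.044, against 0.277 in the transcript-like libraries and 1.31 over all 6. TRPC6 took 18636 CPM in doe-milk library 3 and 130 and 126 CPM in the replacer-milk libraries, and CA10 took 544 against 5712 and 5760 CPM. Both genes were chosen after their values were seen. Of the 38 lists, those that passed camera were ribosomal proteins (median −1.46) and heat shock (median −1.32), both lower in replacer milk. None passed with an estimated correlation.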

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

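The comparisons within a library kind, library kind as a term and the summed libraries were chosen after the data were seen. Over all 6 libraries, 0 genes passed in edgeR, also with each library left out (0 to 0), and with the replicate block. DESeq2 called 2 and library kind as a term 1, LOC108637881, at 0 to 2.28 CPM in doe milk and 0.0385, 368 and 383 CPM in replacer milk. The 25 lists became 8 at 1 CPM or more in every library (fewer genes tested), 1 with library kind as a term, 0 with an estimated correlation and 0 with fry. Leaving out 1 library gave 13 to 27, with 13 without doe-milk library 1 and 14 without doe-milk library 2. Other settings gave 20 to 26, among them 26 with the replicate block. The labels do not say whether replicate numbers pair the samples. Deviations of same-numbered libraries correlated at 0.899, −0.891 and 0.912. These signs followed library kind, since doe-milk library 2 and replacer-milk library 1, of the same kind, correlated at 0.895. The check therefore cannot show or exclude a pairing.

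The number of marker lists lower in replacer milk was 8 to 11 of 12. The 9 lower lists kept that side in every setting but the transcript-like libraries alone, where 5 of them did. Of 501 values of the 30 genes considered over all libraries, 499 kept their direction and side of the threshold, TNNC2 passed with DESeq2, and RPL38 turned to 0.043 with library kind as a term, where the cause was not tested. In the transcript-like libraries the 3 called genes became 5 with RLE, 5 with upper quartile factors, 5 at an adjusted p of 0.10, 90 with no filter, 143 with DESeq2, 1 with dispersions not robust, 0 with limma voom and 0 at 1 CPM or more in every library. The cause was not tested. Their 11 lists became 0 with an estimated correlation and 0 with fry. With ranks 9 were kept, neutrophils and erythroid cells were lost, and complement and oxidative phosphorylation were gained. At 1 CPM or more in every library 10 were kept, the erythroid list had too few members to test and 3 were gained, and other settings kept all 11. Without doe-milk library 1, list medians with no test were −0.78 for the interferon response, −0.39 for immediate early genes, −0.41 for platelets, −0.31 for the cell cycle and −0.79 for mitochondrially encoded transcripts. Without doe-milk library 2 they were −0.72, −0.83, −0.11, −0.12 and −0.04. Of 404 values of the 45 genes considered there, 364 stayed the same and none changed direction. With no filter or DESeq2, 15 genes passed that had not (29 values). In other settings, 7 values of the 3 called genes lost their call, and 4 without a doe-milk library moved by more than the doe-milk spread. The span-proportional libraries hold 313, 360 and 344 mitochondrial counts, so that low levels there are imprecise.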

Other observations

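The tests in this part were all chosen after the results were seen. The doe-milk libraries with measured transcripts differed from each other in the medians of several gene lists, but little in that of the interferon response. A median does not show how far single members differed. From doe-milk library 1 to 2, the median log2 difference was 0.70 for cytotoxic T and NK cell markers, 0.76 for mitochondrially encoded transcripts, −0.78 for dendritic cell markers and −0.60 for cholesterol synthesis genes, against −0.003 for the interferon response. From doe-milk library 1 to replacer-milk library 1, the interferon response differed by −0.72 and from doe-milk library 2 by −0.78. These are differences between single libraries with no test.

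Counts in doe-milk library 3 and replacer-milk libraries 2 and 3 followed gene span. Feed as the cause is argued against by the labels as they stand, since doe-milk library 3 correlated at 0.883 with a replacer-milk library and at no more than 0.383 with the other doe-milk libraries. An exchange of the labels of doe-milk library 3 and replacer-milk library 1 would make kind and feed coincide and was not excluded. Unspliced transcripts of the same cells are argued against, since counts per kb correlated with transcript counts per kb at no more than 0.157 across genes. Nuclear DNA in place of transcripts is a candidate explanation. Genes silent in the transcript-like libraries had at least 0.784 of the counts per kb of the most expressed genes. Some abundant genes stood far higher, which DNA of even density would not give. UBB had 21970, 45999 and 41429 counts per kb in doe-milk library 3 and replacer-milk libraries 2 and 3, and ACTB 1584.5, 2035 and 1878. The autosomal medians were 18.5, 18.3 and 18.1, and B2M had 21.5, 14.3 and 20.8. Whole-cell DNA would also carry many mitochondrial genomes, and mitochondrial genes had only 1.49 to 1.72 times the autosomal counts per kb, which leaves the source of these reads open.

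Replacer-milk libraries 2 and 3 differed by a chi-square of 2.80 per degree of freedom, 2.15 for genes with few counts and 7.20 for those with the most. A library divided or sequenced again would give 1, or near 2 if both mates of a read pair were counted, and these values cannot be told apart from 2 DNA-like libraries of near-equal makeup. No biological explanation was tested.

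The lower interferon genes of replacer-milk library 1 may reflect the feed, but only 1 replacer-milk library held measured transcripts, so the feed and that animal cannot be told apart. With the exchange of labels left open above, the comparison would be among doe-fed kids. Scaling of the libraries is argued against, since it moves all genes of a library alike, and the interferon median lay at −0.73 from that of random lists matched on expression. Fewer monocytes in that library stay open. The monocyte markers had a median of −0.22 and a spread of 0.63 (SD over members), against the interferon median of −0.74. That spread is of single markers, not the error of their median, so it cannot decide the question. Against doe-milk library 1 alone the monocyte median was −0.071, and against doe-milk library 2 alone it was 0.064, without a test. The neutrophil markers were lower in replacer-milk library 1 too (median −0.43). Whether this bears on the interferon genes was not tested.

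Of the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, the split by feed called 0 genes, as few as any, and the split by library kind 17842, which points to a structure of the samples. For lists, 4 of the 10 splits called at least as many as the 25 of the split by feed, and the highest other was 27, given by library kind and by 1 split that did not follow it. The fewest called by any split was 21.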
